A study of Nicotiana tabacum with 6 samples.

How the data were processed

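Messenger RNA was sequenced from seedlings of cultivated tobacco (Nicotiana tabacum), an allotetraploid species whose genome joins those of a pair of wild ancestors. Per the series design text, control seedlings received a Hoagland-type nutrient solution with 7.5 mM ammonium nitrate and low nitrogen seedlings the same solution with 0.75 mM, for 15 days with fresh solution every 7 days. There were 3 libraries in each group. The labels do not say whether the libraries came from separate plants or cultures, so that p-values measure only the spread between these 6 samples, part of which may be technical. The labels name the sampled material only as seedling and do not give the organ.

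Per the labels' protocols, RNA was extracted with a column kit, polyadenylated RNA was used, and libraries were built with a SMARTER mRNA kit. HISAT2, a spliced aligner, is named in the submitters' processing notes. Its version, the counting tool, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited table holds raw whole-number counts per gene for 69500 genes, with an identifier of the Nitab4.5 gene set and, for 44455 genes, a symbol that the authors deposited beside it. The symbols are not unique, since 10135 distinct symbols cover those 44455 genes. Genes of 1 symbol may include near-identical copies, between which the counting may have split reads. The identifier is therefore printed with each symbol. None of the identifiers (0) matched the RefSeq gene table of another tobacco assembly (ASM71507v2), so no coordinates are given.

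Total counts per library ran from 13027374 to 15620067. All computation started from the deposited counts. Genes were kept by edgeR's filterByExpr, which left 38482, and libraries were scaled by TMM factors. The groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 with no fold minimum. Fold changes are low nitrogen over control on the log2 scale. Levels of single genes are CPM (library counts scaled to a common total) after TMM scaling, given as mean ± SD over 3 libraries. Summed levels of gene lists are CPM without TMM scaling. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same counts as alternatives.

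Gene lists were tested with camera (preset inter-gene correlation of 0.01, lists with at least 5 tested members, Benjamini-Hochberg over lists), with camera at an estimated correlation, and with fry. The test, the 55 list topics, the alternatives and the rule for named genes were fixed before the data were examined. The table gives no gene descriptions, so the topics were turned into patterns on the symbols after the table was seen, from the symbol column alone and before any test. A further list, the nicotine enzymes without the berberine bridge family, was added at that point, which makes 56 lists, 28 of them marked as core lists.

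The rule for named genes took, for each core list, the member with the smallest p among those past the threshold and a further member, which was the next smallest p in the opposite direction or, with at least 4 members past the threshold, in the same direction. Where no member passed, it took the member with the highest mean CPM, given as values only. It also took the 6 largest increases and 6 largest decreases among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a characterised product description, counting each description once. Since edgeR placed no gene past the threshold, the second part named none. The same rule was then applied to the calls of DESeq2, with a symbol that is a gene name in place of the product description. Genes past the threshold when adjusted over their list alone were named as well. Both of these choices were made after the edgeR count was seen, as was the naming of the genes with the smallest edgeR p.

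The procedure was tested on simulated data, in which 200 of the 38482 genes were changed by known folds in libraries with the real means and depths. edgeR recovered 6 of 67 genes changed 2-fold (8.96%), 53 of 67 changed 4-fold (79.1%) and 64 of 66 changed 8-fold (97.0%), with 10 false calls among 133. DESeq2 recovered 24, 61 and 66 genes of those sizes, with 88 false calls among 239. limma-voom recovered 5, 49 and 56, with 4 false calls among 114. In a simulation of the same comparison with 20 lists over 38013 tested genes, camera called the changed list and 0 of the other lists, both with the preset and with an estimated correlation. The changed list held 40 genes, all changed 2-fold. Genes were drawn independently of each other, so that the simulation cannot show how often lists of correlated genes are called by mistake.

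The alternatives were median-of-ratios (RLE) and upper-quartile factors, no filter beyond a total above 0, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2, limma-voom, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and summed counts of genes with identical symbols for the lists. Library structure was repeated with a prior count of 0.5 in place of 2 and on the 1000 most variable genes. Alternatives chosen after the data were seen were robust estimation, covariates for photosynthesis transcripts and for the first principal component, leaving out both libraries with the highest photosynthesis sums, summed counts for single genes, the alternatives of the list-alone count and of the count at an unadjusted p under 0.05, and DESeq2 and limma-voom without each library.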

Results

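Seedlings of tobacco grown with 7.5 mM ammonium nitrate were compared with seedlings grown with 0.75 mM, to measure how a low nitrogen supply over 15 days changed messenger RNA levels. The data were counts of 69500 genes in 3 control and 3 low nitrogen libraries. Control replicates 1 to 3 held 13027374, 13873200 and 13811218 counts, and low nitrogen replicates 1 to 3 held 13602774, 15620067 and 14628012. Between 44587 and 46169 genes had at least 1 count in a library. The 10 most abundant genes took 1.85% to 2.66% of the counts. Genes with the symbols of organelle-encoded genes took 0.0889% to 0.110%, and whether each is encoded in an organelle was not checked.

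The control libraries were not alike. Control replicates 1 and 2 correlated at r = 0.966 across genes, which are not independent replicates (log2 CPM), whereas control replicate 3 correlated with them at 0.927 and 0.919. The low nitrogen libraries correlated with each other at 0.941 to 0.953. The first principal component held 44.6% of the variance and placed control replicates 1 and 2 at -79.9 and -74.1, control replicate 3 at 41.3, and the low nitrogen replicates at 86.5, 24.4 and 1.86. Within each group every pair of libraries differed by far more than counting noise (chi-square of at least 13.04 per degree of freedom). This value cannot tell separate plants from separate libraries of the same RNA. All 6 libraries were counted as separate samples.

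Transcripts of the photosynthetic apparatus were scarce and differed most within the control group. The summed level of 67 light-harvesting genes was 55.0, 32.6 and 941 CPM in control replicates 1 to 3 and 432, 193 and 63.6 CPM in low nitrogen replicates 1 to 3. The 89 genes of photosystem and electron transport subunits gave 91.6, 65.6 and 1059 CPM in the controls and 764, 330 and 140 CPM in low nitrogen. Root marker genes were at 265 ± 12.7 CPM in controls and 268 ± 32.6 CPM in low nitrogen (SD, n = 3). QPT (Nitab4.5_0000742g0010), an enzyme of NAD synthesis and of the nicotine pathway, which is active in roots, was at 855 ± 189 CPM in controls and 803 ± 72.7 CPM in low nitrogen.

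**Figure D1:**
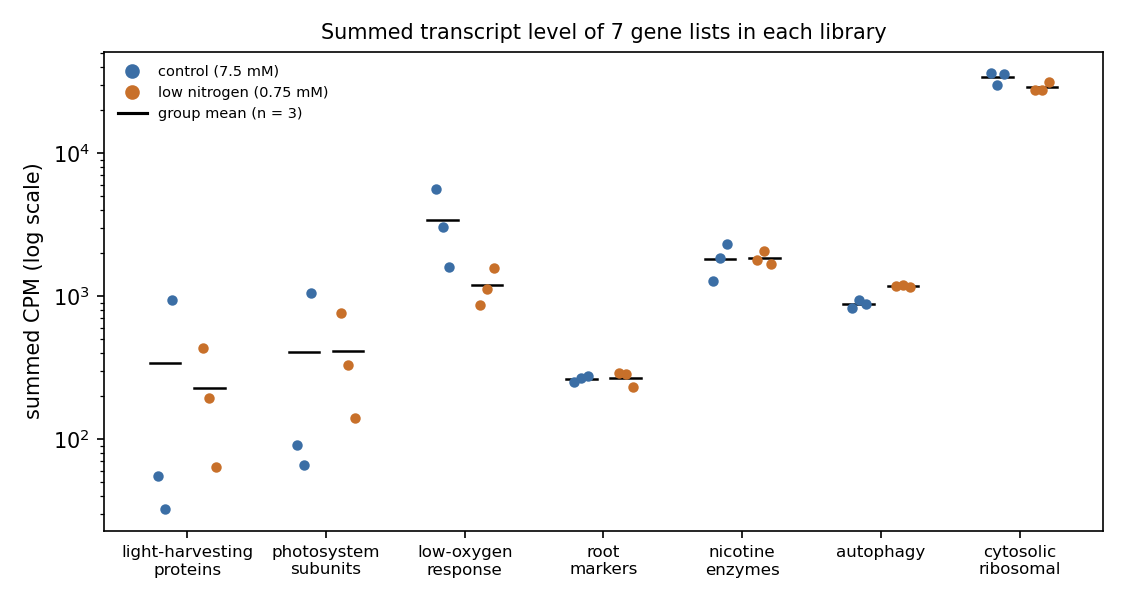
Summed CPM without TMM scaling (vertical axis, log scale) of 7 gene lists in each library, with 1 point per library and a bar at the mean of each group (n = 3). Light-harvesting transcripts spanned 32.6 to 941 CPM within the control group, whereas autophagy transcripts were at 1165 to 1198 CPM in all 3 low nitrogen libraries and at 826 to 942 CPM in controls.

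The genes with the smallest p included a transcription factor, an enzyme of lysine breakdown and an enzyme of sulfur assimilation. MYB24 (Nitab4.5_0001041g0130), a MYB transcription factor, was at 2.02 ± 0.335 CPM in controls and 11.6 ± 0.868 CPM in low nitrogen (SD, n = 3), a log2 fold change of 2.51 (SE 0.20). AASS (Nitab4.5_0001114g0030), the bifunctional enzyme that starts lysine breakdown, was at 20.7 ± 4.56 and 91.4 ± 9.08 CPM. APS4 (Nitab4.5_0000977g0040), an ATP sulfurylase, was at 34.1 ± 1.39 and 9.48 ± 2.26 CPM, a log2 fold change of -1.85 (SE 0.19). With edgeR's quasi-likelihood test 0 of the 38482 genes passed the threshold, and the smallest adjusted p, shared by 6 genes that include these, was 0.138. It placed 11 past the threshold without control replicate 3. At an unadjusted p under 0.05 there were 2349 genes higher and 2178 lower in low nitrogen, 4527 in all. The count at an unadjusted p under 0.05 was 2210 without control replicate 1 and 2539 without low nitrogen replicate 1. limma-voom also placed 0 genes past the threshold (smallest adjusted p 0.137, with 4472 at an unadjusted p under 0.05), and 1 without control replicate 3.

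DESeq2 placed 565 genes past the threshold, 257 higher and 308 lower in low nitrogen, with 4543 genes at an unadjusted p under 0.05. Over all genes tested, 18.2% had no overlap between the groups, against 10% by chance, and genes are not independent replicates. The DESeq2 count was 200, 341 and 1637 without control replicates 1, 2 and 3 in turn, and 191 and 1126 without low nitrogen replicates 1 and 3. In the simulation described with the methods DESeq2 made 88 false calls among 239, so that single genes past its threshold are less certain than the nominal rate. The 6 largest decreases by the naming rule were ADH2 (Nitab4.5_0021429g0010), TPPG (Nitab4.5_0003531g0040), CYP73A14, UGPA (Nitab4.5_0001735g0060), XTH5 (Nitab4.5_0003353g0040) and RBOHB (Nitab4.5_0006988g0020). XTH5 was highest in control replicate 3, and the others fell from control replicate 1 to control replicate 3. RBOHB was at 250, 78.3 and 27.8 CPM in control replicates 1 to 3. In low nitrogen replicates 1 to 3 RBOHB was at 5.88, 5.75 and 21.4 CPM.

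With adjustment over the list alone, 47 entries in 17 of the 56 lists passed the edgeR threshold, against 0 over all genes tested. This count was 15, 23 and 205 without control replicates 1, 2 and 3, and 13, 31 and 74 without low nitrogen replicates 1, 2 and 3. Camera with the preset correlation placed 22 of the 56 lists past the threshold, 9 shifted up and 13 down in low nitrogen. In the same test, splits of the libraries that mix the groups gave 11 to 26 lists. The count of 22 alone therefore does not show an effect of nitrogen supply. With an estimated correlation camera placed 0 (5 at an unadjusted p under 0.05, smallest adjusted p 0.422), and fry placed 0 (8 at an unadjusted p under 0.05, smallest adjusted p 0.0668). fry's test for change in either direction placed 17 lists past the threshold. Those of them not past the camera threshold were MYB factors and pathogenesis-related proteins (fry adjusted p 0.0173 each), WRKY factors (0.0296) and heat shock proteins (0.0456). Lists of abscisic acid, nicotine, amino acid transport, sucrose and cell wall loosening genes were also among them (0.0423 each). Without both control replicate 3 and low nitrogen replicate 1, the libraries with the highest photosynthesis sums, a setting chosen after the data were seen, the camera calls of 10 of the 22 lists ended. These were nitrogen recycling (adjusted p 0.0609), nitrate-responsive regulators (0.10), NAC factors (0.118), lignin (0.162), aquaporins (0.164), proteasome (0.368), peroxidases (0.407), cell cycle (0.506), cellulose and pectin (0.624) and antioxidant enzymes (0.762). In the same setting 7 other lists passed, which made 19, 13 up and 6 down. These were light-harvesting (2.05e-05), photosystem (1.36e-16), pathogenesis-related (0.00488), nicotine (0.0141), starch synthesis (0.0371), protease (0.0421) and sucrose genes (0.0422). With counts summed over identical symbols, calls ended for the NRT1/PTR family (0.434), nitrate-responsive regulators (0.465), general phenylpropanoid (0.465), antioxidant enzymes (0.368), starch breakdown (0.222), flower and pollen markers (0.139), peroxidases (0.132), lignin (0.0917) and proteasome (0.0917), besides those named with their lists. A covariate for photosynthesis transcripts ended the calls of general phenylpropanoid (0.0842), antioxidant enzymes (0.0829) and starch breakdown (0.0741), and added photosystem (0.000724), chlorophyll synthesis (0.0109), cell wall loosening (0.0151), WRKY (0.0216), ammonium transport (0.0416) and sucrose genes (0.0443). The first principal component as a covariate ended those of the NRT1/PTR family (0.987), proteasome (0.987), starch breakdown (0.895), lignin (0.483), peroxidases (0.390), chlorophyll breakdown and senescence (0.284), antioxidant enzymes (0.193), flower and pollen markers (0.193) and general phenylpropanoid (0.168). It added ammonium transport (0.000130), chlorophyll synthesis (2.14e-10), plastid ribosomal proteins (0.00655), pathogenesis-related proteins (0.0173), WRKY factors (0.00158) and cell wall loosening (0.000488) in the direction they had, and 4 lists in the opposite direction, which were light-harvesting (1.51e-40), photosystem (3.00e-49), Calvin cycle (0.000887) and auxin genes (0.0173). Both covariates were also chosen after the data were seen. The photosynthesis covariate was the mean log2 CPM of the tested light-harvesting and photosystem genes, so that its photosystem call rests in part on that list itself.

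**Figure D2:**
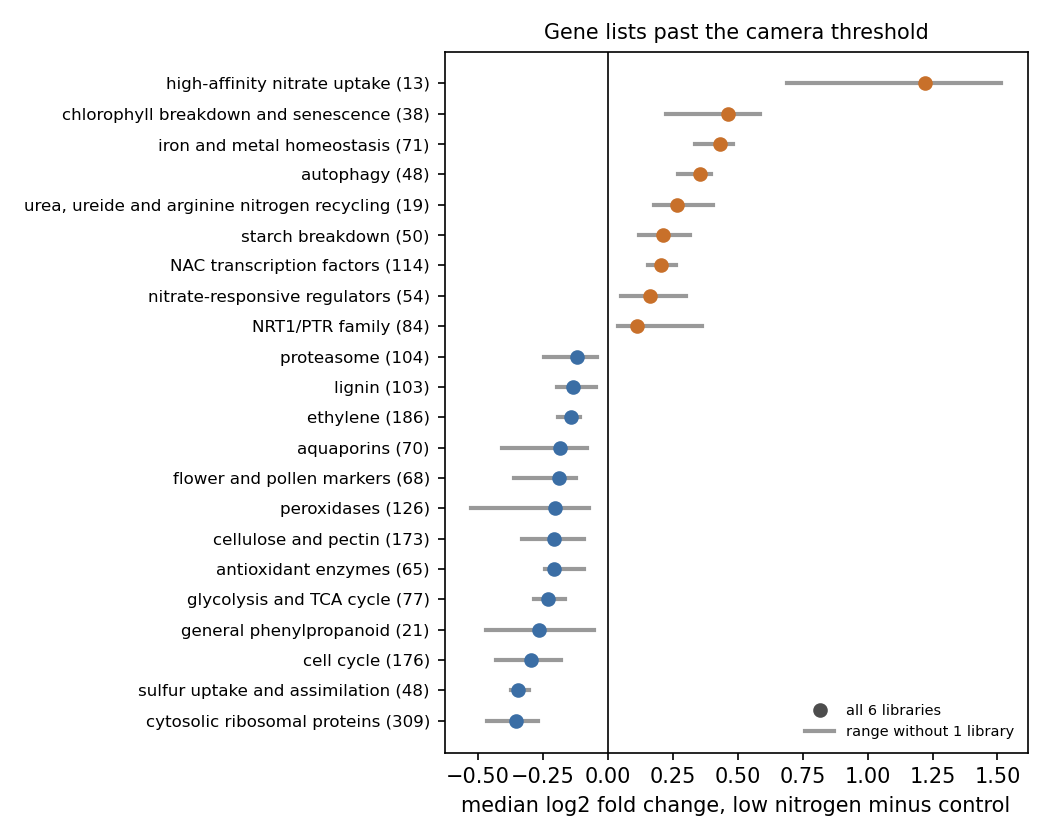
Median log2 fold change (horizontal axis, low nitrogen minus control) of the 22 gene lists past the camera threshold, with the number of tested genes in parentheses; points are medians over all 6 libraries and bars the range when 1 library was left out. High-affinity nitrate uptake had the highest median (1.22) and cytosolic ribosomal proteins the lowest (-0.35).

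High-affinity nitrate uptake genes were shifted up in low nitrogen (camera adjusted p 3.51e-07, and adjusted p = 0.484 with an estimated correlation). These genes encode NRT2 transporters, which take up nitrate at low external concentrations, and their NRT3 partner proteins. The fold change was above 0 for 12 of 13 tested genes, with a median log2 value of 1.22, and 5 passed the threshold when adjusted over the list alone (4 to 5 when any 1 library was left out). The median was 0.69 without control replicate 1 and 0.81 without low nitrogen replicate 2. NRT2.6 (Nitab4.5_0000567g0030) was at 0.794 ± 0.560 CPM in controls and 10.2 ± 6.78 CPM in low nitrogen (SD, n = 3), with a log2 fold change of 3.66 (SE 0.78) and a DESeq2 adjusted p of 0.000120. A second NRT2.6 gene (Nitab4.5_0000567g0010) held 3 counts over the controls and 120 over the low nitrogen libraries, a ratio of 35.6 with a 95% interval of 11.9 to 175, which covers counting error only (from the exact Clopper-Pearson interval). NRT2.2 (Nitab4.5_0005323g0010) was at 0.222 ± 0.122 and 5.26 ± 6.18 CPM, the latter set mostly by low nitrogen replicate 2 at 12.4 CPM. The tested NRT2 gene with the most counts, another NRT2.2 gene (Nitab4.5_0001523g0010), did not rise. It held 6012 counts over the controls and 6220 over the low nitrogen libraries, a scaled ratio of 0.92 (95% interval for counting error 0.888 to 0.953). NRT3.2 (Nitab4.5_0003741g0010) was at 25.1 ± 13.3 and 66.8 ± 25.1 CPM. The most abundant member, another NRT3.2 gene (Nitab4.5_0008037g0050), was at 312 ± 97.4 and 319 ± 66.0 CPM, a log2 fold change of 0.03 (SE 0.27). Summed over all 22 genes of the list, the level was 788.7 ± 319 CPM in controls and 948 ± 360 CPM in low nitrogen. With counts summed over identical symbols the list had fewer than 5 members and was not tested. NRT2 genes may include near-identical copies, and how reads were divided between such copies is not given in the sources used here.

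Other carriers of nitrogen compounds differed in both directions. AMT1-3 (Nitab4.5_0003474g0010), an ammonium transporter, was at 51.9 ± 7.45 CPM in controls and 84.3 ± 9.31 CPM in low nitrogen (SD, n = 3; log2 fold change 0.70, SE 0.16), and was the single one of 7 tested ammonium transporters past the threshold over the list alone (2 without control replicate 2, 1 without low nitrogen replicate 1 and 0 without each other library). In the NRT1/PTR family of nitrate and peptide carriers, 52 of 84 genes had fold changes above 0 (median log2 value 0.11, camera adjusted p 0.0272, and adjusted p = 0.749 with an estimated correlation). NPF8.1 (Nitab4.5_0000744g0200) was at 23.5 ± 1.93 and 40.2 ± 3.18 CPM and was the 1 member past the threshold over the list alone (7 without control replicate 3, 1 without low nitrogen replicate 1 and 0 without each other library). NPF6.2 (Nitab4.5_0003531g0060) was at 17.8 ± 14.5 and 3.0 ± 1.19 CPM. The family call ended without control replicate 1 (0.0906), low nitrogen replicate 1 (0.101) or low nitrogen replicate 2 (0.0883), and with no filter on low counts (0.0994). Its median was 0.041 without control replicate 1, 0.36 without control replicate 3 and 0.28 without low nitrogen replicate 3, and its summed level lay the other way, at 1850 ± 277 CPM in controls and 1712 ± 315 CPM in low nitrogen. Among 71 amino acid carriers, 4 were higher and 2 lower over the list alone, with 0 left without control replicate 1, control replicate 2, low nitrogen replicate 1 or low nitrogen replicate 2, 17 without control replicate 3 and 7 without low nitrogen replicate 3. The higher ones were 2 LHT1 genes, PROT3 and CAT2 (Nitab4.5_0004148g0060, 42.3 ± 2.52 and 64.1 ± 5.47 CPM). The lower ones were 2 AATL1 genes, of which Nitab4.5_0001506g0090 was at 87.9 ± 14.6 and 33.9 ± 12.7 CPM. As lists, the ammonium and amino acid carriers were not past the camera threshold (adjusted p 0.177 and 0.0818).

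Among genes of primary nitrogen assimilation, 2 of the ammonium assimilation list were lower and 2 of asparagine and glutamate catabolism higher with DESeq2, and 0 passed with edgeR, also over each list alone. Over the list alone, ammonium assimilation had 4 genes without control replicate 3 and 3 without low nitrogen replicate 2. Asparagine and glutamate catabolism had 6 without control replicate 3, 2 without low nitrogen replicate 2 and 1 without control replicate 2, and nitrate reduction had 2 without low nitrogen replicate 2. GLN1-1 (Nitab4.5_0000574g0130), a cytosolic glutamine synthetase, was at 209 ± 133 CPM in controls and 46.4 ± 17.8 CPM in low nitrogen (SD, n = 3; log2 fold change -2.17, SE 0.56, DESeq2 adjusted p 0.00246), with overlap between the groups. GLT1 (Nitab4.5_0002492g0040), a glutamate synthase, was at 422 ± 141 and 270 ± 54.1 CPM. The nitrate reductase gene NIA (Nitab4.5_0002857g0010) was at 429 ± 91.9 and 266 ± 127 CPM, with an edgeR adjusted p of 0.471. AS1 (Nitab4.5_0000839g0060), an asparagine synthetase, was at 20.7 ± 12.1 and 125 ± 53.9 CPM (log2 fold change 2.59, SE 0.58, DESeq2 adjusted p 0.000195), while ASN2 (Nitab4.5_0000630g0010) was at 361 ± 40.04 and 343 ± 159 CPM. Both are on the list of asparagine and glutamate catabolism, which therefore also holds genes of asparagine synthesis. AS1 was among its 2 higher genes with DESeq2. The lists of nitrate reduction, ammonium assimilation, and asparagine and glutamate catabolism had median log2 values of 0.03, -0.13 and -0.01 and camera adjusted p of 0.677, 0.260 and 0.50. Ammonium assimilation was past the threshold, shifted down, without control replicate 3 (0.0125) or low nitrogen replicate 2 (0.0147).

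Genes that recycle nitrogen from urea, ureides and arginine were shifted up, with 13 of 19 fold changes above 0 and a median log2 value of 0.27 (camera adjusted p 0.0104, and adjusted p = 0.444 with an estimated correlation). XDH1 (Nitab4.5_0006994g0020), xanthine dehydrogenase, was at 42.3 ± 2.93 and 63.3 ± 2.64 CPM, and ARGAH2 (Nitab4.5_0000457g0100), an arginase, at 5.59 ± 1.24 and 10.9 ± 1.41 CPM. Both passed over the list alone (5 genes without control replicate 2, 1 without control replicate 1 and 0 without each other library). AAH (Nitab4.5_0000973g0030), allantoate amidohydrolase, was at 79.1 ± 15.4 and 125 ± 20.97 CPM. The call ended without control replicate 3 (0.0747), without low nitrogen replicate 3 (0.0755), and with summed symbols (0.0917), and the median was 0.41 without low nitrogen replicate 2.

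Autophagy genes, whose products carry cell contents to the vacuole for breakdown, were shifted up together (camera adjusted p 4.20e-09, and adjusted p = 0.444 with an estimated correlation). Of 48 genes, 45 had fold changes above 0, with a median log2 value of 0.36, and 18 were higher and 0 lower at an unadjusted p under 0.05. The summed level was 882 ± 57.9 CPM in controls and 1178 ± 17.5 CPM in low nitrogen (SD, n = 3). ATG8G (Nitab4.5_0000712g0240), a ubiquitin-like protein of the autophagosome membrane, was at 24.5 ± 6.25 and 44.9 ± 5.78 CPM, and the most abundant member, ATG2 (Nitab4.5_0003503g0010), at 53.2 ± 8.62 and 68.6 ± 8.67 CPM. With fry the adjusted p of the list was 0.0668. Over the list alone 0 genes passed with edgeR (smallest adjusted p 0.0548; 2 without control replicate 3), and 2 passed over all genes with DESeq2.

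Genes of chlorophyll breakdown and senescence were also shifted up, 30 of 38 with fold changes above 0 and a median log2 value of 0.46 (camera adjusted p 0.000878, and adjusted p = 0.729 with an estimated correlation). A SAG21 gene (Nitab4.5_0007333g0010) was at 2.53 ± 0.868 CPM in controls and 17.7 ± 11.3 CPM in low nitrogen, and a more abundant SAG21 gene (Nitab4.5_0002820g0100) at 201 ± 54.0 and 257 ± 153 CPM. The summed level was 622 to 658 CPM in the controls and 1274, 855 and 602 CPM in low nitrogen replicates 1 to 3. The sum in low nitrogen replicate 3 was thus close to that of the lowest control. The median was 0.23 without control replicate 1 and 0.28 without low nitrogen replicate 1. The call ended with the first principal component as a covariate (adjusted p 0.284). The NAC transcription factors, a family with many regulators of senescence, had 83 fold changes above 0 and 31 below (median log2 value 0.20, camera adjusted p 0.00299, and adjusted p = 0.729 with an estimated correlation). Over that list alone 3 genes passed (3 without control replicate 3 or low nitrogen replicate 2, 1 without low nitrogen replicate 3 and 0 without each other library), all with the symbol ONAC010, of which Nitab4.5_0000040g0110 was at 13.5 ± 2.82 and 34.9 ± 1.69 CPM. The call of this family ended without low nitrogen replicate 3 (adjusted p 0.0755).

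Cytosolic ribosomal protein genes were shifted down as a group by a small amount (camera adjusted p 1.83e-21, and adjusted p = 0.729 with an estimated correlation). The estimated correlation between these genes was 0.561, far above the preset 0.01, so that the smaller p overstates the evidence. Of 309 genes, 286 had fold changes below 0, the median log2 value was -0.35, and 100 were lower and 1 higher at an unadjusted p under 0.05. Their summed level was 34085 ± 3527 CPM in controls and 28941 ± 2066 CPM in low nitrogen (SD, n = 3). The groups overlapped in this sum, with control replicate 2 at 30017 CPM and low nitrogen replicate 3 at 31324 CPM. RPL9D (Nitab4.5_0002123g0080) was at 55.7 ± 1.58 and 37.9 ± 3.50 CPM and was the 1 member past the DESeq2 threshold (adjusted p 0.0323). RPS3A (Nitab4.5_0006849g0010), the most abundant, was at 631 ± 67.7 and 473 ± 84.3 CPM. Genes of the cell cycle followed the same direction, with 143 of 176 fold changes below 0 and a median log2 value of -0.29 (camera adjusted p 0.000160, and adjusted p 0.749 with an estimated correlation). That call ended without the 2 libraries with the highest photosynthesis sums (0.506), and the median was -0.18 without low nitrogen replicate 1. Proteasome genes had 85 of 104 fold changes below 0 and a median log2 value of -0.12 (camera adjusted p 0.00747, and adjusted p 0.749 with an estimated correlation), a call that ended without low nitrogen replicate 1 (0.404, median -0.040); the median was -0.24 without low nitrogen replicate 3. The estimated correlation was 0.265 for the cell cycle list and 0.387 for the proteasome list. Plastid ribosomal protein genes had a median log2 value of -0.10 and a camera adjusted p of 0.621.

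Genes of ethylene synthesis and response were shifted down in low nitrogen, with 107 of 186 fold changes below 0 and 79 above (median log2 value -0.14, camera adjusted p 0.000169, and adjusted p = 0.444 with an estimated correlation). ACS1 (Nitab4.5_0002381g0080), an ACC synthase, which makes the precursor of ethylene, was at 25.2 ± 15.2 CPM in controls and 2.70 ± 1.40 CPM in low nitrogen (SD, n = 3; log2 fold change -3.22, SE 0.53, DESeq2 adjusted p 2.15e-07). It was at 42.4, 19.7 and 13.5 CPM in control replicates 1 to 3 and 1.68, 2.12 and 4.30 CPM in low nitrogen replicates 1 to 3. The sum of low-oxygen genes was likewise highest in control replicates 1 and 2 and lowest in low nitrogen replicates 1 and 2. Control replicate 3 and low nitrogen replicate 3, which differed for ACS1, were alike in that sum (1588 and 1586 CPM). ACO (Nitab4.5_0009635g0010), an ACC oxidase, which makes ethylene from that precursor, was at 90.9 ± 25.8 and 34.98 ± 8.11 CPM. The receptor gene EIN4 (Nitab4.5_0000342g0270) was at 25.7 ± 9.51 and 7.22 ± 2.34 CPM, and the response factor ERF5 (Nitab4.5_0000470g0230) at 18.6 ± 4.41 and 5.29 ± 0.629 CPM. Genes with the symbol ERF094 went both ways, Nitab4.5_0003571g0020 with a log2 fold change of -2.26 and Nitab4.5_0001088g0130 with 1.63. Over the list alone, 9 of 186 genes were lower and 1 higher. The number past that threshold was 1, 1 and 44 without control replicates 1, 2 and 3, and 3, 2 and 23 without low nitrogen replicates 1, 2 and 3.

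Mineral nutrition lists differed in direction. Sulfur uptake and assimilation genes had 35 of 48 fold changes below 0 (median log2 value -0.35, camera adjusted p 0.000268, and adjusted p 0.422 with an estimated correlation and 0.0640 with summed symbols). APS4 was the 1 member past the threshold over the list alone (adjusted p 0.000837; 11 genes without control replicate 3, 2 without low nitrogen replicate 2 and 1 without each other library), with a DESeq2 adjusted p of 4.81e-12. Iron and metal genes had 53 of 71 fold changes above 0 (median log2 value 0.43, camera adjusted p 1.96e-06, and adjusted p 0.584 with an estimated correlation). F6'H1 (Nitab4.5_0001401g0120), which makes coumarins that roots release under iron shortage, was at 53.9 ± 10.7 CPM in controls and 115 ± 5.37 CPM in low nitrogen and was the 1 member past the threshold over the list alone (11 without low nitrogen replicate 3, 2 without control replicate 1, 1 without control replicate 2 and 0 without each other library). ZIP10 (Nitab4.5_0013314g0010), a metal transporter, was at 5.66 ± 1.06 and 48.0 ± 37.2 CPM. HAK2 (Nitab4.5_0000175g0420), a potassium transporter, was at 16.5 ± 1.36 and 36.1 ± 3.77 CPM (log2 fold change 1.13, SE 0.14, adjusted p 0.00371 over the list alone with edgeR), while the median of 63 potassium channels and transporters was -0.01 on the log2 scale. PHT1-4 (Nitab4.5_0001005g0070), a phosphate transporter, was at 9.46 ± 0.798 and 32.1 ± 15.4 CPM, while the phosphate starvation list had a median log2 value of -0.04. The camera adjusted p of these last lists was 0.505 and 0.443.

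**Figure D3:**
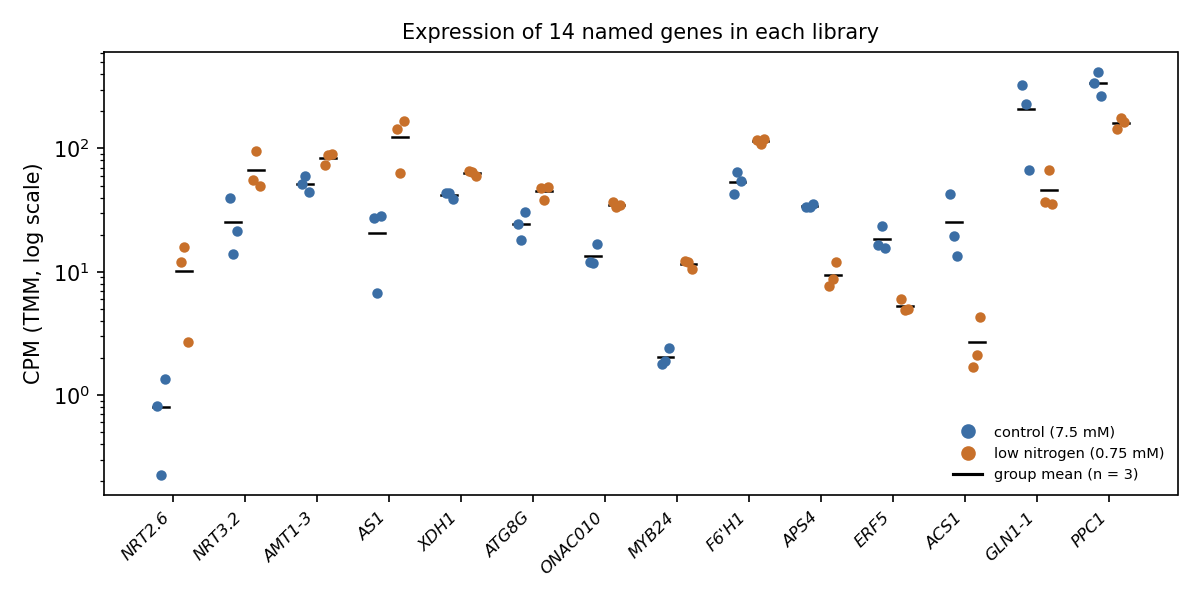
Expression of 14 named genes (vertical axis, TMM-scaled CPM, log scale), with 1 point per library and a bar at the mean of each group (n = 3); none passed the edgeR threshold over all genes tested. AS1 had means of 20.7 CPM in controls and 125 CPM in low nitrogen, and APS4 means of 34.1 and 9.48 CPM.

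Genes of glycolysis and the TCA cycle were shifted down, with 57 of 77 fold changes below 0 and a median log2 value of -0.23 (camera adjusted p 0.000127, and adjusted p = 0.729 with an estimated correlation). PPC1 (Nitab4.5_0000035g0130), a phosphoenolpyruvate carboxylase, was at 342 ± 75.6 CPM in controls and 162 ± 17.2 CPM in low nitrogen (SD, n = 3). PFP-ALPHA1 (Nitab4.5_0000464g0120), a subunit of a phosphofructokinase, was at 322 ± 56.6 and 162 ± 23.6 CPM, and the enolase gene ENO1 (Nitab4.5_0000646g0160) at 45.9 ± 2.47 and 23.9 ± 6.10 CPM. Summed over the list, the level was 9816, 8699 and 7590 CPM in control replicates 1 to 3 and 5662, 6621 and 7513 CPM in low nitrogen replicates 1 to 3. Genes that respond to low oxygen, on a list written after the data were seen, ranked the libraries in the same order, at 5579, 3050 and 1588 CPM and 870, 1120 and 1586 CPM. The 3 glycolysis genes passed over the list alone (2 genes without control replicate 3 or low nitrogen replicate 3 and 0 without each other library). Starch breakdown genes had 37 of 50 fold changes above 0 and a median log2 value of 0.21 (camera adjusted p 0.0427, and adjusted p 0.749 with an estimated correlation), a call that ended without control replicate 2 (0.485, median 0.12), low nitrogen replicate 1 (0.118, median 0.13) or low nitrogen replicate 3 (0.116). Starch synthesis and sucrose genes had median log2 values of 0.15 and 0.10 and camera adjusted p of 0.486 and 0.0956, and were past the threshold without both control replicate 3 and low nitrogen replicate 1 (0.0371 and 0.0422).

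Lists of cell wall and phenolic genes differed in whether they passed the camera threshold. Cellulose and pectin genes had 117 of 173 fold changes below 0 (median log2 value -0.20, camera adjusted p 0.00240, and adjusted p 0.749 with an estimated correlation), and their call ended without control replicate 3 (0.0891, median -0.092) or low nitrogen replicate 1 (0.0939, median -0.10); the median was -0.33 without low nitrogen replicate 2. The pectin methylesterase gene PME61 (Nitab4.5_0000481g0160) was at 7.20 ± 1.91 CPM in controls and 1.26 ± 0.357 CPM in low nitrogen (SD, n = 3), and CSLG2 (Nitab4.5_0000342g0310), a cellulose synthase-like gene, at 6.36 ± 0.969 and 21.3 ± 6.62 CPM. Both passed over the list alone (3 genes without control replicate 3, 2 without low nitrogen replicate 2, 1 without control replicate 1 and 0 without each other library). Peroxidases had a median log2 value of -0.20 (camera adjusted p 0.00319, and adjusted p 0.749 with an estimated correlation), a call that ended without low nitrogen replicate 1 (0.302, median -0.072), with a median of -0.53 without low nitrogen replicate 2. Lignin genes had a median of -0.13 and general phenylpropanoid genes a median of -0.26, each with a camera adjusted p of 0.0430 and an adjusted p of 0.749 with an estimated correlation. The lignin call ended without control replicate 2 (0.598, median -0.046), low nitrogen replicate 1 (0.302, median -0.070) or low nitrogen replicate 3 (0.0758), and with a filter of 1 CPM in 3 libraries (0.0627). The phenylpropanoid call ended without control replicate 1 (0.0957), control replicate 2 (0.498, median -0.052), low nitrogen replicate 1 (0.248, median -0.13) or low nitrogen replicate 2 (0.130), and the median was -0.47 without control replicate 3. CYP73A14 (Nitab4.5_0000404g0200), a cinnamate hydroxylase, was at 78.4 ± 85.2 and 4.71 ± 3.23 CPM, with control replicate 1 at 175 CPM. Among 107 genes of cell wall loosening, XTH23 was higher and XTH26, XTH16 and an XTH5 gene lower over the list alone (6 genes without control replicate 3, 5 without control replicate 2 and 0 without each other library). That list had a median of -0.10 and a camera adjusted p of 0.0644, and was past the threshold without control replicate 1 (0.0455, median -0.15), control replicate 2 (0.000819, median -0.24) or low nitrogen replicate 2 (0.0147, median -0.33). Flavonoid and anthocyanin genes had a median of -0.19 and a camera adjusted p of 0.579.

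Further lists past the camera threshold depended on single libraries. Aquaporins had a median log2 value of -0.18 (camera adjusted p 0.00213, and adjusted p 0.729 with an estimated correlation and 0.0755 without low nitrogen replicate 3). Their median was -0.29 without control replicate 1, -0.079 without control replicate 3 and -0.41 without low nitrogen replicate 2. Flower and pollen markers had a median of -0.19 (camera adjusted p 0.0121, and adjusted p 0.729 with an estimated correlation, 0.0590 without low nitrogen replicate 1 and 0.106 without low nitrogen replicate 3), which was -0.12 without control replicate 3 and -0.36 without low nitrogen replicate 2. Antioxidant enzymes had a median of -0.21 (camera adjusted p 0.0430, and adjusted p 0.729 with an estimated correlation), while their summed level was 6762 ± 1603 CPM in controls and 8865 ± 1556 CPM in low nitrogen, so that the sum lay the other way. That call ended without control replicate 1 (0.10, median -0.099), control replicate 3 (0.350), low nitrogen replicate 1 (0.184, median -0.091) or low nitrogen replicate 2 (0.0883). Nitrate-responsive regulators had 35 of 54 fold changes above 0 and a median of 0.16 (camera adjusted p 0.0206, and adjusted p 0.729 with an estimated correlation), a call that ended without control replicate 1 (0.0661, median 0.052), control replicate 3 (0.108, median 0.085) or low nitrogen replicate 2 (0.0528). The median was 0.30 without control replicate 2 and 0.089 without low nitrogen replicate 1. NLP5 (Nitab4.5_0009395g0020), a NIN-like regulator of nitrate responses, was at 114.05 ± 47.3 CPM in controls and 111.15 ± 40.1 CPM in low nitrogen (SD, n = 3).

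The lists of light-harvesting, photosystem and Calvin cycle genes had camera adjusted p above the threshold, and their direction differed between settings. Light-harvesting genes had 35 of 39 fold changes below 0, with a median log2 fold change of -0.72 and a mean of -0.77, although camera placed them upward (adjusted p 0.669), and photosystem and electron transport genes had a median of -0.27 and a mean of -0.24 with camera again upward (adjusted p 0.0855). CAB50 (Nitab4.5_0002814g0030), a light-harvesting protein gene, was at 28.5 ± 45.9 CPM in controls and 12.9 ± 13.3 CPM in low nitrogen (SD, n = 3), so that any difference was smaller than the spread between replicates. Without control replicate 3 both lists were past the threshold and upward, with medians of 2.83 (camera adjusted p 2.18e-12) and 2.90 (7.65e-21). Without control replicate 2 light-harvesting genes were past it downward (median -1.37, adjusted p 0.000755), and without low nitrogen replicate 3 photosystem genes upward (median 0.06, adjusted p 0.00224). Without both control replicate 3 and low nitrogen replicate 1 both were past it upward, with medians of 1.56 (2.05e-05) and 1.53 (1.36e-16). With the photosynthesis covariate photosystem genes were past it upward (median 0.27, adjusted p 0.000724), and with the first principal component both lists were past it downward (medians -2.33 and -1.91). The photosynthesis covariate was the mean of the genes of these same lists, so that its call cannot bear on nitrogen supply. Calvin cycle genes had a median of 0.09 (camera adjusted p 0.528, and 0.0284 with a median of 0.56 without control replicate 3). Of 20 tested genes, 14 had fold changes above 0 and 6 below. The summed level of the list lay the other way, at 919 ± 19.1 CPM in controls and 773 ± 28.7 CPM in low nitrogen. Most of that sum came from a pair of TKL-1 genes. Nitab4.5_0003912g0020 had TMM-scaled means of 405 CPM in controls and 272 CPM in low nitrogen, and Nitab4.5_0001329g0110 of 321 and 247 CPM. The lower sum therefore mainly reflects these genes and does not describe the list. Chlorophyll synthesis genes had 23 of 30 fold changes below 0 and a median of -0.17 (camera adjusted p 0.0644). They were past the threshold without control replicate 1 (0.0354), control replicate 2 (0.00289, median -0.33) or low nitrogen replicate 1 (0.0120), and with no filter on low counts (0.0475). HEMA1 (Nitab4.5_0010352g0010), the glutamyl-tRNA reductase that begins the pathway, was at 10.9 ± 1.62 and 5.64 ± 0.157 CPM, and GSA (Nitab4.5_0001089g0010), the enzyme of the next step, at 25.2 ± 2.03 and 16.3 ± 1.36 CPM. Both passed over the list alone (3 genes without low nitrogen replicate 3, 1 without control replicate 3 and 0 without each other library).

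The list of nicotine synthesis and transport had a camera adjusted p above the threshold. It holds QPT and nadB genes, whose products also serve NAD synthesis, and genes of the berberine bridge family. Of 29 genes of nicotine synthesis and transport, 20 had fold changes above 0, with a median log2 value of 0.29 and a camera adjusted p of 0.0696 (0.0259 with a median of 0.19 without control replicate 1, 0.0136 with a median of 0.46 without control replicate 3, and 0.0141 without both control replicate 3 and low nitrogen replicate 1). The 9 tested genes outside the berberine bridge family, which include QPT, had a median of 0.03 and a camera adjusted p of 0.998. One gene of the berberine bridge family (At4g20820, Nitab4.5_0001181g0090) was at 0.686 ± 0.815 CPM in controls and 4.48 ± 1.34 CPM in low nitrogen (SD, n = 3), with a DESeq2 adjusted p of 0.0279.

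The other 5 hormone lists, and those of pathogenesis-related proteins, WRKY and MYB factors, glutathione S-transferases and heat shock proteins, had camera adjusted p above the threshold. Median log2 values and camera adjusted p were 0.06 and 0.413 for cytokinin, 0.05 and 0.780 for auxin, 0.11 and 0.169 for abscisic acid, -0.02 and 0.669 for gibberellin, and -0.03 and 0.311 for jasmonate. Within these lists, the cytokinin receptor gene AHK2 (Nitab4.5_0000996g0050) was at 44.1 ± 3.67 CPM in controls and 73.5 ± 6.53 CPM in low nitrogen (SD, n = 3; DESeq2 adjusted p 0.00171). Another AHK2 gene (Nitab4.5_0001774g0030), the most abundant of the cytokinin list, was at 59.2 ± 11.6 and 69.3 ± 19.5 CPM (DESeq2 adjusted p 0.835). OPR1 (Nitab4.5_0001799g0060), an oxophytodienoate reductase, was at 33.7 ± 8.80 and 13.5 ± 6.0 CPM (DESeq2 adjusted p 0.0191). The most abundant jasmonate gene, OPR2 (Nitab4.5_0001279g0030), lay the other way, at 738 ± 161 and 1232 ± 287 CPM (DESeq2 adjusted p 0.122). Among gibberellin genes, the receptor gene GID1A (Nitab4.5_0001949g0070, 7.76 ± 2.23 and 17.8 ± 3.14 CPM) and the repressor gene RGL3 passed over the list alone (1 gene without control replicate 3 and 0 without each other library). Medians and adjusted p were 0.12 and 0.0818 for pathogenesis-related proteins, 0.16 and 0.0644 for WRKY factors, 0.04 and 0.294 for MYB factors, -0.07 and 0.486 for glutathione S-transferases and -0.15 and 0.0818 for heat shock proteins. The 2 WRKY genes past the threshold over their list alone (3 without low nitrogen replicate 2, 2 without low nitrogen replicate 3, 1 without control replicate 3 and 0 without each other library) had the symbol WRKY60 and were lower, one of them (Nitab4.5_0002568g0030) at 11.3 ± 0.232 and 4.58 ± 0.993 CPM. MYB24 was the 1 MYB gene past that threshold (3 genes without low nitrogen replicate 3 and 1 without each other library). With 1 library left out, camera placed further lists past the threshold. These were WRKY factors without control replicate 1 (0.0195), control replicate 2 (0.0161) or low nitrogen replicate 2 (0.000845), pathogenesis-related proteins without control replicate 1 (0.0126) or low nitrogen replicate 1 (0.00114, median 0.30), and heat shock proteins without control replicate 2 (0.0483, median -0.22) or low nitrogen replicate 1 (0.0199). Abscisic acid genes (0.0133, median 0.17) and MYB factors (0.0160, median 0.11) passed without control replicate 2, and glutathione S-transferases (0.00175, median -0.24) without low nitrogen replicate 3.

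The remaining lists describe tissue and general cell functions. Medians and camera adjusted p were 0.08 and 0.584 for root markers, 0.01 and 0.792 for leaf epidermis and cuticle markers, 0.00 and 0.621 for vascular and xylem markers, 0.21 and 0.328 for histones, 0.03 and 0.780 for proteases, and -0.04 and 0.486 for genes with the symbols of organelle-encoded genes. In 11 of the 56 lists, none of them past the threshold, the median, the mean and the direction given by camera did not share one sign. Besides both photosynthesis lists these were nitrate reduction, asparagine and glutamate catabolism, potassium transport, heat shock proteins, gibberellin, auxin, nicotine enzymes outside the berberine bridge family, and the vascular and leaf epidermis markers.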

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

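Tests chosen only after the data were seen were robust estimation, both covariates, leaving out both libraries with the highest photosynthesis sums, summed counts for single genes, alternatives of the list-alone count and of the count at an unadjusted p under 0.05, and DESeq2 and limma-voom without each library. The edgeR count of 0 genes (4527 at an unadjusted p under 0.05) was also 0 with RLE or upper-quartile factors, either filter, an adjusted p under 0.01, a log2 fold change of at least 1, robust estimation, the first principal component as a covariate, summed symbols, limma-voom, and without both of those libraries. It was 6 with the photosynthesis covariate, 565 with DESeq2, and 0 to 11 without 1 library (11 without control replicate 3); with limma-voom it was 0 to 1. DESeq2 called 191 to 1637 genes without 1 library. Of the 565 genes, 481 were called again without control replicate 3, but 170 without control replicate 1 and 169 without low nitrogen replicate 1. The 47 entries over lists alone became 13 to 205 without 1 library, 91 without both libraries, 101 with the photosynthesis covariate and 104 with the principal component. The 22 lists were 16 to 26 without 1 library, 10 with summed symbols, where fewer genes were tested and high-affinity nitrate uptake could not be, and 0 with an estimated correlation or fry. The cause of the other changes was not tested. The first principal component held 44.6% of the variance, 45.02% at a prior count of 0.5 and 62.2% on the 1000 most variable genes. Medians of light-harvesting genes ran from -1.58 to 2.83 without 1 library, called down without control replicate 2 (-1.37). With the principal component, which itself separates the groups in part, camera called lists down that it had placed upward, with medians for light-harvesting (-2.33), photosystem (-1.91), Calvin cycle (-0.45) and auxin genes (-0.12), and its direction turned without a call for the NRT1/PTR family (0.13), general phenylpropanoid (0.18) and starch breakdown (-0.029). Of 94 named genes, 82 kept the sign of their fold change in every setting run. The other 12 were all among the genes named for the highest mean CPM in the 28 core lists. Genes named for passing a threshold in these data were picked in a way that by itself favours a stable sign. Few counts limited the scarce nitrate transporters, one of which held 3 in the controls.

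With the replicate number as a block, edgeR gave 0 genes (3056 at an unadjusted p under 0.05), 33 entries over lists alone and 25 lists; the block ended the calls of general phenylpropanoid (adjusted p 0.0634) and antioxidant enzymes (0.0913). It added calls, all upward, for light-harvesting (0.0365, median 1.03), photosystem (0.000661, median 1.05), nicotine (0.0318), pathogenesis-related (0.000213) and WRKY genes (0.0414). Deviations from the group means correlated at -0.316, 0.104 and -0.274 for replicates 1, 2 and 3. No control library correlated best with the low nitrogen library of its own number. These values gave no sign that the numbers pair the samples, but with 3 libraries in each group they cannot exclude it.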

Other observations

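The tests chosen only after their result was seen were those of library size and of nitrogen supply on photosynthesis transcripts, those of nitrogen and oxygen supply on low-oxygen transcripts, and the splits counted by genes; the genes in the next paragraph were picked after their values were seen.

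Of the genes higher in low nitrogen among the 40 with the smallest edgeR p, 6 are given here as values. They were picked from a larger number that also held CYP94C1 (Nitab4.5_0002547g0010), HAK2 and ONAC010, and were not tested as a group. Besides AASS (Nitab4.5_0001114g0030), a second AASS gene (Nitab4.5_0000055g0100) was at 53.9 ± 8.23 CPM in controls and 169 ± 24.9 CPM in low nitrogen (SD, n = 3; log2 fold change 1.65, SE 0.18). HGO (Nitab4.5_0003077g0020), homogentisate dioxygenase of tyrosine breakdown, was at 22.0 ± 2.45 and 41.6 ± 1.26 CPM, and BCE2 (Nitab4.5_0000695g0030), a subunit of the complex that breaks down branched-chain amino acids, at 13.5 ± 2.07 and 30.5 ± 3.73 CPM. BXL4 (Nitab4.5_0003754g0020), a xylosidase, was at 9.84 ± 2.43 and 39.9 ± 8.62 CPM, and ARA1 (Nitab4.5_0001942g0140), an arabinose kinase, at 19.3 ± 2.72 and 53.8 ± 6.66 CPM. The edgeR adjusted p of these 6 genes lay between 0.138 and 0.205. The list of asparagine and glutamate catabolism, which also holds genes of asparagine synthesis, had a median log2 value of -0.01. Without control replicate 3 the first AASS gene and MYB24 were among the 11 genes past the edgeR threshold, with log2 fold changes of 2.29 and 2.65; GABA-TP1 and COR413PM1 were also higher there, and 2 LBD40 genes, UGT73C1, OCT5, CBSX6, At1g05000 and DOGL1 lower.

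Genes that respond to low oxygen had their highest sums in control replicates 1 and 2, while control replicate 3 and low nitrogen replicate 3 were alike. The list (ADH, PDC, PCO4, LBD40, HB and ALAAT genes) was written after the pattern had been seen and was not tested between the groups. It summed to 5579, 3050 and 1588 CPM in control replicates 1 to 3 and to 870, 1120 and 1586 CPM in low nitrogen replicates 1 to 3. ADH (Nitab4.5_0001821g0060), alcohol dehydrogenase, was at 1317, 513 and 189 CPM in the controls and at 31.4, 60.8 and 148 CPM in low nitrogen. The tables argue against a few genes taking most of the counts, since the 10 most abundant genes took 1.25 times the share in control replicate 1 that they took in low nitrogen replicate 1. The nitrogen supply stays open, because the ratio of 3.51 between the highest and lowest control libraries was of the size of the 2.86 between the group means. A different oxygen supply to the roots may also have contributed. In the part of the list without ADH and PDC the median log2 ratio of control replicate 1 to low nitrogen replicate 1 was 0.73, between the bounds set for and against it, with 22 of 32 genes above 0.

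Photosynthesis transcripts (light-harvesting and photosystem genes together) summed to 98.2 CPM in control replicate 2 and to 2000 CPM in control replicate 3. Library size does not account for this, since the largest total was 1.199 times the smallest. Nitrogen supply cannot be the whole cause, since the ratio of 20.4 lay within 1 group and the group means differed by 1.17 times. A candidate explanation is that the samples held different shares of shoot tissue, a hypothesis tested on 26 YABBY and stomatal genes listed before their values were seen. Their sum was 3.96 times higher in control replicate 3 than in control replicate 2 (142 and 36 counts), short of the 5 times set in advance, and in low nitrogen replicate 1, with 1195 CPM of photosynthesis transcripts, it was 1.98 CPM against 2.59 CPM in control replicate 2. The genes lie near the detection limit, so that the explanation stays open; greening of the sampled tissue was not tested.

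The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With edgeR the real split gave 0 genes past the threshold (4527 at an unadjusted p under 0.05) and the highest other split 2, and since no count lies below 0, all 10 splits necessarily gave at least as many as the real one. At an unadjusted p under 0.05 the other splits gave 623 to 4708 genes, so that 1 split that mixes the groups exceeded the 4527 of the real one; limma-voom gave 0 for the real split. With DESeq2 the real split gave 565 genes and the highest other 1014, and 3 of the 10 splits gave at least as many as the real one. With camera the real split gave 22 lists and the other splits 11 to 26, and 4 of the 10 splits gave at least as many. Camera at the preset correlation thus called lists in every split that mixed the groups.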
